A study of Canis lupus familiaris and Canis lupus with 31 samples.

How the data were processed

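DNA from white blood cells was measured on 31 Agilent 2-colour arrays with 417074 spots each, with the animal in Cy5 and the reference in Cy3 and without dye swaps. The groups follow the sample labels: 9 German Shepherds, 14 dogs of a breed panel and 1 gray wolf against a Boxer, 6 dogs with seizures each against a control of the same breed, and 1 Blackmouth Cur against itself. The sex of the Boxer is not specified in the labels. Per the file headers, the scanner files hold spot signals as intensity, background-subtracted and dye-normalized with Agilent Feature Extraction 10.7.1.1. The deposited value table holds log10 ratios of Cy5 over Cy3, with column medians from -0.001141 to 0.009211. It equals the log10 ratio of the scanner files in every spot (largest difference 0), so its scale, centring and direction are known. The log10 ratio recomputed from the processed signals, used here, differed from it by more than 0.01 in 118 to 893 of 411496 spots per array, and by at most 1.10; the value table was therefore run as an alternative. The genome build is not given in the sources used here, and positions are those of the array design. Gene names were therefore not assigned, and the planned gene list overlap was not run.

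Log2 ratios were taken from the processed signals of 396798 autosomal and 14698 X probes, without control spots and spots flagged as outliers, and centred on the autosomal median of each array. Noise is the spread of differences between neighbouring probes, on the scale of 1 probe. Single probes more than 4 SD from their neighbours were moved to 2 SD, and each chromosome was segmented by penalised least squares (own code, penalty 3 times the natural log of the number of probes, segments of at least 3 probes). A call is an autosomal segment of 5 or more probes with an absolute mean log2 ratio of 0.3 or more. Calls of different arrays that overlap by 1 bp or more form a region, and the core of a region is the stretch covered by the most arrays. Segments of X beyond the pseudoautosomal part were called by the same thresholds after each array was centred on its own median there, and are given apart. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.

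The median green signal per array ranged from 64.8 to 257.7 and averaged 110.2. The segmentation and the bin tests were tested on simulated data. Of 80 planted segments per size, 35.0%, 95.0% and 100% were found at a log2 ratio of 1 over 5, 10 and 20 probes, and 2.5%, 16.2% and 75.0% at 0.6, with 7 other calls. Of 100 planted bins per size, 74% were found at 0.3 and 100% at 0.6 for German Shepherds against the panel, and 17% and 84% for the seizure arrays, with 9 and 1 false calls.

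Numbers of calls in German Shepherds and panel dogs, and X ratios of males and females, were compared with exact two-sided permutation tests over all splits (817190 and 735471). Bins of 5 neighbouring autosomal probes (79345) were tested with limma, German Shepherds against the panel and the seizure arrays against 0, with Benjamini-Hochberg adjustment. A bin was called at an adjusted p under 0.05 and an absolute difference of 0.2 or more. Similarity within German Shepherds is the mean pairwise Pearson correlation over the 832 bins inside copy number regions, tested one-sided with 100000 permutations of the group labels. Fisher's exact tests of carrier numbers, correlations of calls with noise the comparison of regions on different chromosomes and the spread of the shared cores against 1000 windows each were added after the data were seen. The p-values measure the spread between samples.

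Named by a rule written before the data were examined were the 10 regions called in the most Boxer-referenced arrays (ties by the carriers' absolute mean), the 10 called bins with the largest difference in each direction for German Shepherds, the seizure regions called the same way in 2 or more arrays (at most 10), the largest call of each seizure array and the 5 largest wolf calls that no dog array shares. Positions stand in for genes.

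Alternatives covered normexp background correction (limma, offset 50) of the median spot and background signals, the value table, call thresholds, probe numbers, the penalty, long-range trend, flagged spots, bin size, slide, sex, round and scan day in the model, and arrays left out. The plan named mean signals for normexp; the files were read for median signals instead. Slides 5 to 8 were hybridised in up to 3 rounds: 8 of 9 German Shepherds fell in round 3, and the panel in rounds 1 and 2.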

Results

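DNA copy number was compared between dogs with array comparative genomic hybridisation, in which Cy5-labelled DNA of an animal and Cy3-labelled reference DNA compete for the same probes, so that a log2 ratio above 0 means more copies in the animal than in the reference. The DNA came from white blood cells. Of the 31 arrays, 24 were run against DNA of a Boxer: 9 German Shepherds, 14 dogs of a breed panel (each of another breed or mix) and 1 gray wolf. A further 6 arrays each set a dog with seizures against a control dog of the same breed, and 1 array set a Blackmouth Cur against itself. Each array carried 396798 autosomal and 14698 X chromosome probes, with a median spacing of 889 bp between autosomal probes. The noise between neighbouring probes averaged 0.29 log2 units (SD 0.06, n = 31) and ranged from 0.21 to 0.50. On average 99.5% of probes were well above background in at least 1 channel, with 97.3% on the lowest array. Apart from the German Shepherds, each breed and the wolf had a single array in its group, so the number of arrays limits the precision of every comparison between groups. Positions are those of the array design, whose genome build is not given in the sources used here, and the files name no genes, so that regions are given by chromosome, start and end.

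The X chromosome set the scale of a known copy number difference. The median log2 ratio over X was -0.03 ± 0.03 in the 16 arrays labelled male (SD) and 0.86 ± 0.02 in the 8 labelled female, with no overlap: males ranged from -0.10 to 0.00 and females from 0.84 to 0.89. The difference of males minus females, -0.89, was far larger than the spread within either sex (exact two-sided permutation p = 1.36e-06, the smallest that 735471 splits can give). With normexp background correction the same difference was -0.54. The sexes parted between positions 6594634 and 6612596 of X: females minus males was 0.00 over the 801 probes before this point and 0.90 over the 13897 probes after it. Before it, in the pseudoautosomal part, males stood at 0.00 ± 0.04 and females at 0.01 ± 0.03. Males were near 0 on both sides of this point, so the Boxer DNA held as many X copies as males did. In the 6 seizure arrays the X median was 0.00 ± 0.05 (SD), and in the self-self array it was -0.04.

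Over all 31 arrays, 499 autosomal segments were called, 221 gains and 278 losses, a mean of 16.1 per array. The self-self array held 1 of them. That call was a loss of -0.31 on chromosome 3, from 56156208 to 56224821, and it lay just past the threshold. The self-self array was less noisy than the average array (0.24 against 0.29 log2 units). As a single array it gives no rate of false calls for the others. The 24 arrays against the Boxer held 366 calls, 152 gains and 214 losses, with a median length of 25.3 kb. Among these, 85 losses lay below -1 and 48 gains above 1. The Chow Chow had the most calls of the panel, 27, of which 20 were losses, followed by the Irish Wolfhound and the Yorkshire-Terrier with 23 each. The Welsh-Corgie had the fewest, 7. The longest call reached 2654 kb and lay in a German Shepherd. Among simulated segments of 10 probes, 95.0% were found at a log2 ratio of 1 and 16.2% at 0.6, so that short or weak changes were mostly below what single arrays can show.

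**Figure D1:**
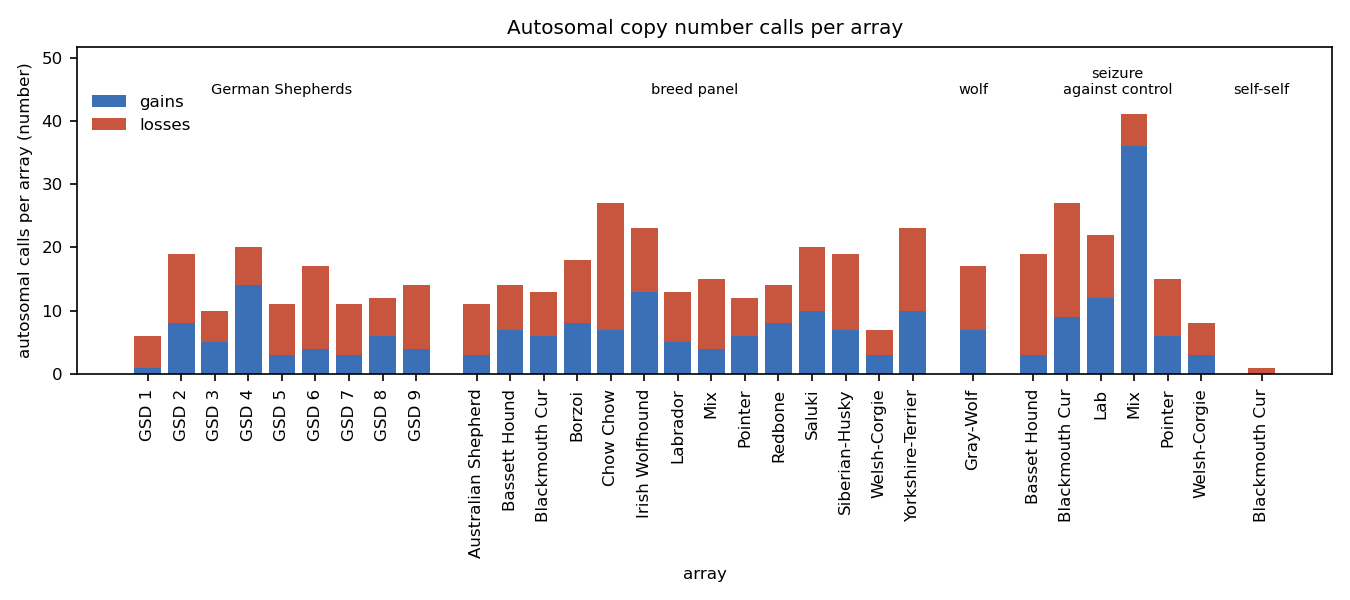
Autosomal gains (blue) and losses (red) called in each of the 31 arrays, as stacked bars of the number of calls, grouped by comparison. The self-self array holds 1 call, the German Shepherds between 6 and 20, the breed panel between 7 and 27 and the seizure arrays between 8 and 41.

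The German Shepherds were first set against the panel by the number of calls. German Shepherds held 13.3 ± 4.58 calls per array (SD, n = 9) and the panel dogs 16.4 ± 5.51 (n = 14). Losses outnumbered gains in both groups: 8.0 ± 2.83 losses and 5.33 ± 3.81 gains in German Shepherds, and 9.43 ± 3.96 losses and 6.93 ± 2.81 gains in the panel. The difference in calls, -3.02, did not exceed the spread between dogs (exact two-sided permutation p = 0.188). It was -9.75, -1.33, -1.25 and -0.83 within the 4 slides that held both groups, and labels permuted within slides gave a two-sided permutation p of 0.168. Counting only calls of at least 0.5 in absolute log2 ratio, German Shepherds had 10.1 ± 3.26 and the panel 13.9 ± 3.96 calls, a difference of -3.75 with an exact permutation p of 0.0292. Slides were hybridised in up to 3 rounds: the panel averaged 13.9 calls in round 1 and 18.9 in round 2 (7 arrays each), while the 8 German Shepherds of round 3 averaged 12.6 and German Shepherd 2, the only one of round 1, had 19. German Shepherd arrays were noisier, at 0.31 ± 0.06 log2 units against 0.28 ± 0.01 in the panel (SD). Over the 23 dogs, calls fell with the noise of the array (Pearson r = -0.45, permutation p = 0.0289, and Spearman rho = -0.43, permutation p = 0.0389). The relation rested on the 2 arrays farthest from the median noise, without which r was -0.26. These were German Shepherds 1 and 8 (6 and 12 calls), the only German Shepherds of slide 5, where the difference was -9.75. With slide means taken off r was -0.47 (p = 0.0347; rho = -0.39, p = 0.0926; r = -0.04 without those 2 arrays), and with round means taken off it was -0.35 (p = 0.0714; rho = -0.27, p = 0.211; r = -0.18 without them), by permutation within batches.

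Calls that overlapped between arrays formed 119 copy number regions, on 37 of the 38 autosomes, of which 64 were lost only, 49 gained only and 6 changed both ways. Most were called in few arrays: 74 regions in a single array, 31 in 2 to 5 arrays and 14 in 6 or more. German Shepherds and panel dogs shared 23 regions, while 22 were called only in German Shepherds, 64 only in the panel and 6 only in the wolf. These are counts of calls, and an array without a call can still be shifted. The chromosome 9 region from 52978307, called in 1 German Shepherd alone, averaged -0.86 in the panel and -1.29 in the wolf. At the chromosome 28 region from 35244143, called in 3 panel dogs alone, German Shepherds ranged from 0.61 to 1.14. Elsewhere this was not so: the chromosome 1 region from 73345529, called in 2 German Shepherds alone, averaged -0.07 in the panel.

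The region called in the most arrays lay on chromosome 17, with a core from 59759435 to 59810133, and was lost against the Boxer in 23 of 24 arrays: its ratio averaged -0.91 ± 0.21 in German Shepherds, -0.78 ± 0.39 in the panel (SD, n = 9 and n = 14) and -0.93 in the wolf. The exception was the Bassett Hound at -0.16, and the deepest loss was that of the Labrador at -1.70. A core on chromosome 6, from 50074590 to 50095521, was lost in 22 arrays at a nearly uniform depth, -0.52 ± 0.08 in German Shepherds and -0.52 ± 0.10 in the panel. There the wolf was lowest of the 24 arrays, at -0.98. Another core of chromosome 6, from 12807958 to 12845215, was lost in 20 arrays, at -0.72 ± 0.14 and -0.79 ± 0.30, but stood at -0.13 in the wolf. A core on chromosome 21, from 29740369 to 29756847, was lost in all 9 German Shepherds, at -4.16 ± 0.49. In the panel it averaged -1.59 ± 1.85, from -4.69 in the Australian Shepherd to 0.20 in the Chow Chow, with 9 of 14 dogs called. It rests on 3 probes.

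Gains were shared less widely. On chromosome 30, from 40816664 to 40821467, 15 arrays were gained, with means of 0.93 ± 0.46 in German Shepherds and 0.49 ± 0.47 in the panel and 1.40 in the wolf. On chromosome 9, from 13462349 to 13478201, 14 arrays were gained, the ratio averaging 1.12 ± 0.33 in German Shepherds and 1.39 ± 0.84 in the panel and reaching 2.69 in the Blackmouth Cur and 2.66 in the wolf. On chromosome 2, from 26047539 to 26061487, 13 arrays were gained, and the Welsh-Corgie alone was lost there, at -0.79. On chromosome 14, from 5302063 to 5803923, a stretch of 502 kb was gained in 14 arrays, at 0.27 ± 0.45 in German Shepherds and 0.47 ± 0.44 in the panel. The last of the 10 most shared regions were losses on chromosome 1 called in 11 arrays each. From 114640117 to 114644526 the ratio was -2.39 ± 1.30 in German Shepherds and -0.85 ± 1.19 in the panel, and from 105839542 to 105840421 it was -0.90 ± 0.59 and -1.47 ± 1.25.

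At these 10 cores the self-self array ranged from -0.22 to 0.32, and the mean of the 6 seizure arrays, which contain no Boxer DNA, from -0.31 to 0.64. Single seizure arrays varied far more, from -3.96 in Welsh-Corgie to 5.71 in Lab at the chromosome 21 core. Between the 23 dogs, 9 of the 10 cores spread more than the 99th percentile of windows with as many probes outside the regions; the exception was the chromosome 6 core from 50074590, with an SD of 0.09 against a limit of 0.12. Carrier numbers of German Shepherds and panel dogs were compared in all 119 regions with Fisher's exact test (two-sided). In 4 regions the unadjusted p lay under 0.05, and in 0 after Benjamini-Hochberg adjustment, where every adjusted p was 1. These 4, named after their values were seen, were a loss on chromosome 27 from 28801827 to 28837571 in 4 German Shepherds and no panel dog (p = 0.0142), a region of chromosome 2 from 86821242 to 87025772 called in 7 panel dogs and no German Shepherd (p = 0.0189), the chromosome 1 region from 114638293 to 114644526 (p = 0.0361) and a region of chromosome 9 from 19567082 to 21507690 called in 8 panel dogs and 1 German Shepherd (p = 0.0397).

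**Figure D2:**
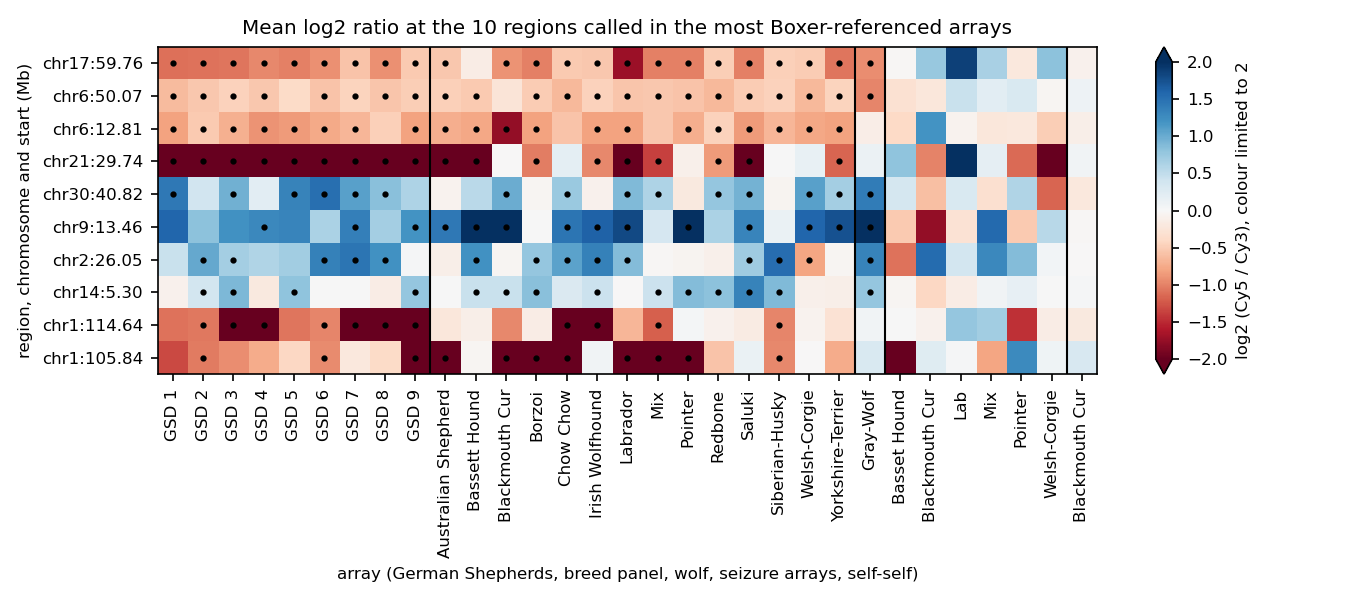
Mean log2 ratio of each of the 31 arrays (columns) at the cores of the 10 regions called in the most arrays against the Boxer (rows, by chromosome and start in Mb), with the colour limited to 2 log2 units; dots mark arrays against the Boxer in which the region was called. The chromosome 17 and chromosome 6 losses run through nearly all Boxer-referenced columns, and the self-self column at the far right stays between -0.22 and 0.32.

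A pair of regions on different chromosomes carried the same values from dog to dog, a comparison chosen after the values were seen. The ratio at the core of the chromosome 9 region, from 21084735 to 21129421, and that at the core of the chromosome 2 region, from 86831830 to 86887822, differed by at most 0.13 in each of the 23 dogs against the Boxer. Both were highest in the Blackmouth Cur (1.30 and 1.27) and the Pointer (1.03 and 1.01) and lowest in the Mix (-1.02 and -0.93). The wolf was the exception, with 0.40 on chromosome 9 and -0.19 on chromosome 2. Over the 24 arrays Pearson r was 0.963 and Spearman rho 0.876 (two-sided permutation p = 1e-05 for both, the smallest that the resamples can give), and r was 0.931 without the 2 arrays farthest from the median. In the 6 seizure arrays, which share no reference, r was 0.998 and rho 0.943 (exact two-sided permutation p = 0.00278 and 0.0167). Of the 945 pairs of regions on different chromosomes that were called in 2 or more arrays, this was the only pair with r above 0.9, and the next highest r was 0.847. These p-values apply to the pair picked as the highest of the 945 and are not corrected for that choice.

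**Figure D3:**
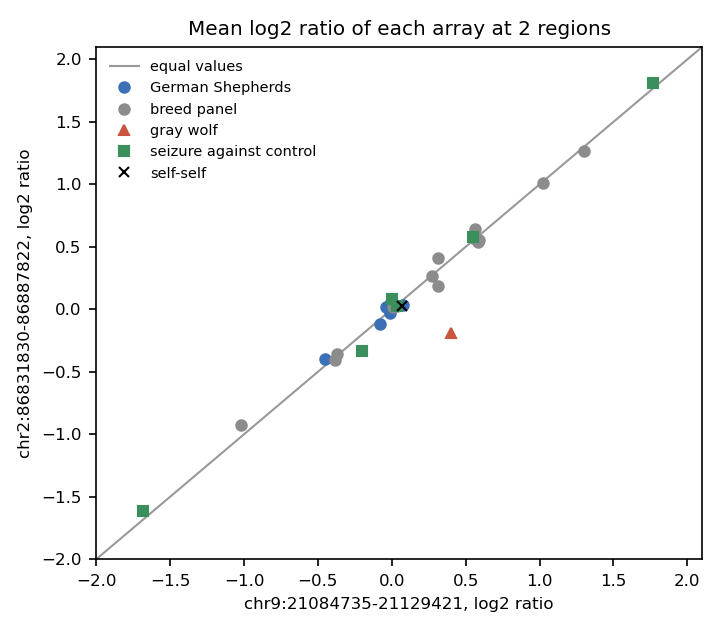
Mean log2 ratio of each of the 31 arrays at the chromosome 9 core (horizontal axis) and the chromosome 2 core (vertical axis), with the line of equal values; symbols and colours give the group of the array. All dogs lie close to the line, and the wolf lies below it at 0.40 and -0.19.

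To find where German Shepherds as a group differ from other dogs, 79345 bins of 5 neighbouring autosomal probes were tested. German Shepherds were lower than the panel in 24 bins and higher in 11. With normexp the balance turned, to 16 lower and 40 higher, and 12 of the 35 bins were called again. The bin with the largest difference lay on chromosome 4, from 17437556 to 17443023. German Shepherds averaged -2.22 ± 1.0 there and the panel -0.06 ± 0.36 (SD, n = 9 and n = 14), a difference of -2.16 (limma, adjusted p = 1.97e-05). With round as a block this difference was -0.53, and German Shepherd 2, the only German Shepherd of a round that held panel dogs, stood at -0.59, inside the panel range of -0.83 to 0.47. On chromosome 21, from 29756788 to 29781699 and next to the shared core described above, the difference was -1.79 (adjusted p = 0.0393). German Shepherds stood at -2.81 ± 0.33 and the panel at -1.03 ± 1.23, from -3.11 to 0.30. A loss reaching this bin was called in 9 of the 14 panel dogs too, and 2 of the 9 German Shepherds lay outside the panel range. The bin was no longer called with slide as a block (adjusted p = 0.081) or with scan day as a random block (0.238). With scan day as a fixed block only German Shepherd 2 (-2.92) and the Australian Shepherd (-3.06) are compared, the only arrays of both groups scanned on the same day, and their difference was 0.14. On chromosome 20, from 30594477 to 30599045, German Shepherds stood at -1.94 ± 0.22 and the panel at -0.55 ± 0.49, a difference of -1.39 (adjusted p = 8.61e-06). The self-self array, without a copy number difference, stood at -0.53 there, near the panel mean. The lowest panel dog reached -2.15, and 2 of the 9 German Shepherds lay outside the panel range. In 3 of the 5 probes the difference had the same sign, and no German Shepherd or panel dog had a called segment there. On chromosome 27, from 28655050 to 28802878, the difference was -1.18 (adjusted p = 0.000966), and this bin overlaps the start of the loss called in 4 German Shepherds. With normexp these 4 differences were -0.60, -0.42, -0.36 and -0.34, all still called. Further bins were lower by smaller amounts: chromosome 34 from 20159439 (-0.51), chromosome 2 from 77401431 (-0.50), chromosome 19 from 20392776 (-0.50), chromosome 2 from 25759749 (-0.46), chromosome 35 from 10375444 (-0.45) and chromosome 14 from 21075733 (-0.41). With normexp these were, in the same order, -0.16, -0.04, -0.07, -0.12, -0.22 and -0.07, and only the chromosome 35 bin kept its call. The chromosome 34 bin kept an adjusted p under 0.05 (limma, 0.0325) and fell only below the minimum difference of 0.2. With scan day as a random block, calls were lost on chromosome 2 from 25759749, chromosome 35 and chromosome 14 (limma, adjusted p = 0.109, 0.0694 and 0.0710).

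Bins higher in German Shepherds differed less. The largest lay on chromosome 3, from 61749103 to 61754296, with 0.67 ± 0.16 in German Shepherds and 0.10 ± 0.28 in the panel, a difference of 0.57 (limma, adjusted p = 0.00491). On chromosome 17, from 60760412 to 60764930, the difference was 0.54 (with slide as a block the call was lost, adjusted p = 0.0638), and on chromosome 6, from 26195589 to 26205850, it was 0.44, with 8 of the 9 German Shepherds above the highest panel dog. The others were on chromosome 34 from 22406859 (0.42, its call lost with slide as a block, adjusted p = 0.0504), chromosome 19 from 18306367 (0.41), chromosome 6 from 16156745 (0.40), chromosome 30 from 24648693 (0.37), chromosome 15 from 65434301 (0.29), chromosome 14 from 3586145 (0.26) and chromosome 18 from 53537838 (0.25). With normexp the bins on chromosome 34 (0.26) and chromosome 15 (0.26) kept their call. Those on chromosome 19 (0.197), chromosome 6 from 16156745 (0.086), chromosome 30 (0.138), chromosome 14 (0.194) and chromosome 18 (0.151) lost it. Chromosome 6 from 16156745 then had an adjusted p of 0.220 (limma). Chromosomes 19, 30, 14 and 18 kept 0.0137, 0.0385, 0.00788 and 0.0182 and fell only below the minimum difference of 0.2. Normexp also narrowed the X difference, from -0.89 to -0.54. With scan day as a random block, among the bins listed from chromosome 34 on, only those on chromosomes 30 and 15 kept their call (limma, adjusted p = 0.0355 and 0.0304). The chromosome 17 bin lost it too (adjusted p = 0.120). No 2 called bins were neighbours, 4 of the 35 lay in a called copy number region, and in 21 of them a single probe carried over 50% of the summed difference. Among the 4 bins with differences above 1, that share was 32.04% on chromosome 4, 30.6% on chromosome 21, 53.6% on chromosome 20 and 36.8% on chromosome 27.

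At an unadjusted p under 0.05, 703 bins passed the minimum difference of 0.2. With slide as a block 25 bins were called, 23 of them among the 35. German Shepherds and panel shared a hybridisation round only through German Shepherd 2, and with round as a block 2 bins were called, neither among the 35. The differences of 15 of the 35 bins were then as large or larger and those of 20 smaller, while their standard errors rose 2.44 times (median), since the contrast then rests on that single array. The bins called with round as a block, named after their values were seen, lay on chromosome 15 from 61170521 (-1.22) and chromosome 22 from 63727115 (0.90). Over all dogs these differences were -0.24 (adjusted p = 0.466) and 0.20 (adjusted p = 0.378), neither called, so they describe German Shepherd 2 and not the group. Scan day as a fixed block leaves German Shepherd 2 against the Australian Shepherd alone, so its 4 calls and its lost calls say nothing about the group. With scan day as a random block, which uses all dogs, 12 bins were called, all among the 35. Within the panel, round 2 against round 1 gave 0 bins in limma, and 1417 at an unadjusted p under 0.05 with the minimum difference.

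**Figure D4:**
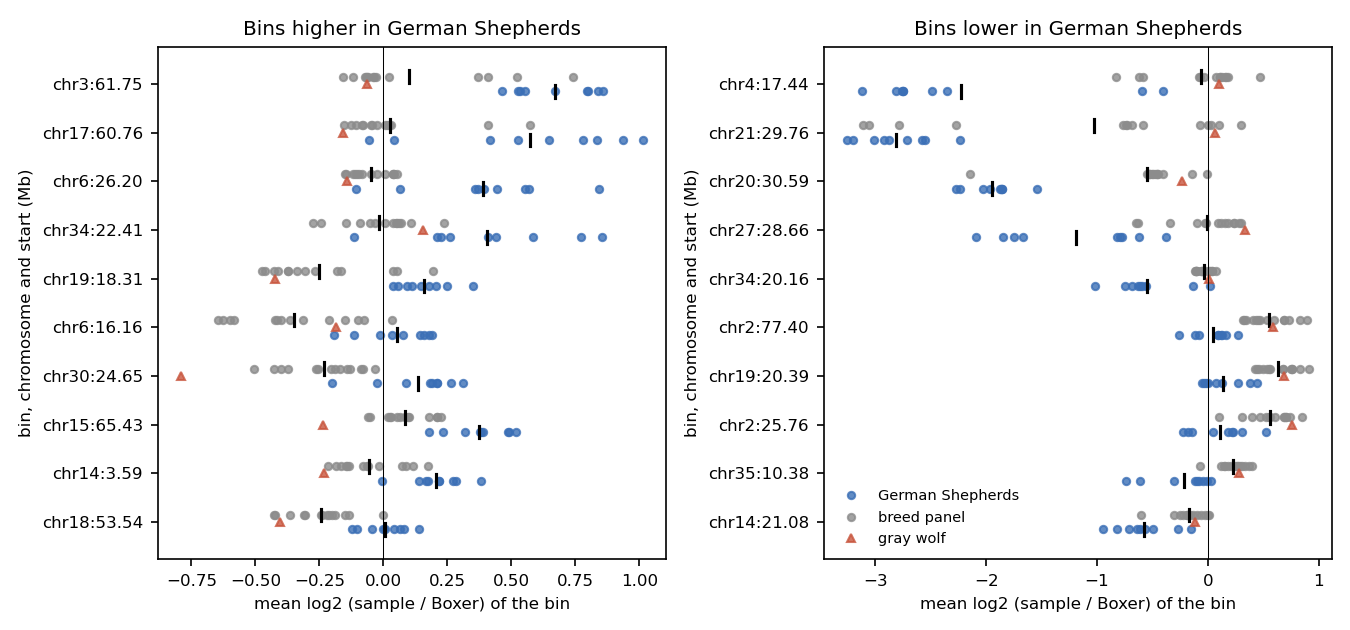
Mean log2 ratio of each German Shepherd (blue), panel dog (gray) and the wolf (red triangle) in the 10 bins with the largest positive (left) and negative (right) difference between German Shepherds and panel; black ticks mark the group means. German Shepherds minus panel is -2.16 at the chromosome 4 bin and 0.57 at the chromosome 3 bin.

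German Shepherds resembled each other more than panel dogs did in the copy number regions. Over the 832 bins inside these regions, the mean correlation between 2 German Shepherds was 0.626, from 0.497 to 0.767 over 36 pairs, and that between 2 panel dogs 0.393, from 0.202 to 0.721 over 91 pairs. The difference of 0.233 was tested by permuting the group labels of the 23 dogs (one-sided permutation p = 3.00e-05). These correlations run across bins, which are not independent replicates. It was not seen with ranks (Spearman, 0.0077, p = 0.423) or over all 79345 autosomal bins (0.0026, p = 0.464), each by the same permutation test. With 8 of 9 German Shepherds alone in round 3, the p does not separate breed from round. German Shepherd 2, hybridised in round 1, correlated at 0.693 with the other German Shepherds and at 0.517 with the 7 panel dogs of its own round. Among panel dogs, pairs of round 1 had a mean r of 0.494, pairs of round 2 0.341 and pairs across rounds 0.373. The closest pair of the panel was the Blackmouth Cur and the Pointer, at 0.721.

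The gray wolf carried 17 calls, of which 12 overlapped a call in at least 1 dog array, seizure arrays included. The other 5, shared with no dog array, were 4 losses and 1 gain. A loss on chromosome 33 from 33569985 (-0.52), named after its value was seen, was called in no dog against the Boxer and is left out of the 5 because a gain of the Mix seizure array (0.38) overlaps it. The deepest, on chromosome 27 from 38555856 to 38563421, stood at -3.87 in the wolf and at -0.22 ± 0.10 in the 23 dogs (SD). It was followed on the same chromosome, from 38564237 to 38721498, by a weaker loss of -0.33, where the dogs stood at 0.02 ± 0.07. The remaining losses lay on chromosome 16 from 10498994 to 10504883 (-1.11, dogs -0.03 ± 0.08) and on chromosome 34 from 33296621 to 35223967 (-0.32, dogs 0.05 ± 0.07). The gain lay on chromosome 11, from 30581235 to 30679683, at 0.83 in the wolf against -0.02 ± 0.09 in the dogs. Each wolf value came from a single array and has no replicate. At all 5 positions it lay outside the range of the 23 dogs. The positions were picked as calls shared with no dog array, which made this likely beforehand.

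The seizure arrays asked whether dogs with seizures differ in copy number from controls of their breed. Over the 6 arrays, 45 bins differed from 0, of which 44 lay below 0 and 1, on chromosome 2 from 68088228 to 68093223, above it (0.41). The largest shifts lay on chromosome 23 from 15124185 to 15126516, at -1.54 ± 0.26 (SD, n = 6, limma adjusted p = 3.59e-05), and on chromosome 31 from 40777506 to 40779289, at -1.28 ± 0.24 (adjusted p = 5.84e-05). The same bins were shifted where no dog with seizures was involved: the self-self array had the same sign in all 45, with a mean of -0.68 against -0.70 in the seizure arrays, and the 24 arrays against the Boxer averaged -0.77 over them. No dyes were swapped, so a shift common to cases and a shift between dyes have the same sign in these 6 arrays.

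**Figure D5:**
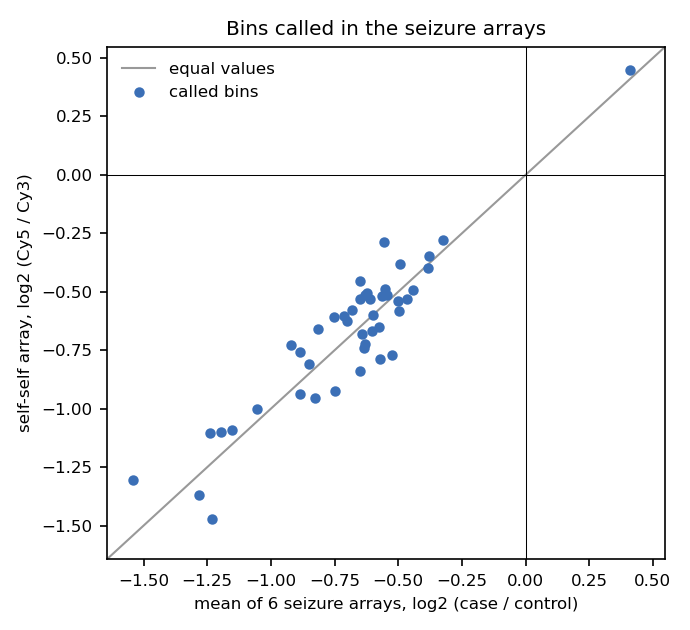
Mean log2 ratio over the 6 seizure arrays (horizontal axis) against the log2 ratio of the self-self array (vertical axis) for the 45 bins called in the seizure arrays, with the line of equal values. All 45 points lie in the quadrants of equal sign, with a median ratio of self-self to seizure value of 0.949.

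Taken array by array, the seizure comparisons held 132 calls, 69 gains and 63 losses, or 22.0 ± 11.3 per array (SD, n = 6). The Mix array alone held 36 of the gains and 5 of the losses, and without it the balance turned to 33 gains and 58 losses. With the self-self profile regressed out, a setting chosen after the results were seen, 98 calls were left. Mix fell from 41 to 26 calls and Pointer from 15 to 2. Blackmouth Cur fell from 27 to 22 and Basset Hound from 19 to 18, while Lab kept 22 and Welsh-Corgie 8. A ratio above 0 can stem from more copies in the case or fewer in the control. The calls formed 95 regions, of which 70 were called in a single array and 14 were called the same way in 2 or more. Of these 14, 9 overlapped a region already called against the Boxer, as did 63 of the 132 calls. The most frequent was the chromosome 17 region from 59756310 to 59846904, which was gained in 4 seizure arrays: Lab (2.01), Welsh-Corgie (0.85), Blackmouth Cur (0.83) and Mix (0.73). A gain on chromosome 18, from 14371351 to 14406520, was called in Pointer (1.19), Lab (0.95) and Blackmouth Cur (0.58). Regions called the same way in 2 arrays included a loss on chromosome 30 from 40813263 to 40821467 in Welsh-Corgie (-1.11) and Blackmouth Cur (-0.65), a gain on chromosome 13 from 5459699 to 5497374 in Lab (0.88) and Basset Hound (0.82) and a loss on chromosome 15 from 55919240 to 55923343 in Blackmouth Cur (-0.86) and Lab (-0.65). On chromosome 2, from 26047539 to 26061487, Blackmouth Cur (1.54) and Mix (1.28) were gained and Basset Hound (-1.09) was lost. On chromosome 4, from 3068484 to 3069833, Blackmouth Cur was lost (-0.91). Basset Hound stood at -0.57 there, within a longer and weaker loss to 3390424 (-0.34). The Mix array was called as a gain over a similarly long stretch, to 3399170 (0.31). Mix and Pointer shared 3 weak gains: on chromosome 4 from 22774693 to 23221025 (0.41 and 0.39), on chromosome 18 from 56278591 to 56385541 (0.38 and 0.36) and on chromosome 33 from 32402006 to 32965527 (0.36 and 0.31). The self-self array, in which no copy number difference can exist, stood at 0.13, 0.14 and 0.08 there. With its profile regressed out, a setting chosen after the results were seen, the means of Mix and Pointer fell from 0.40, 0.37 and 0.34 to 0.26, 0.25 and 0.26, below the minimum of 0.3 for a call.

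The strongest call lay at another position in each of the 6 seizure arrays. The ratio of case to control was 4.76 in Mix on chromosome 21, from 30136353 to 30137428, and 4.57 in Lab on the same chromosome, from 29725864 to 29758128, across the core lost in all German Shepherds, where the panel Labrador stood at -3.99 against the Boxer. It was -4.60 in Blackmouth Cur on chromosome 6, from 43770733 to 43772978, -4.14 in Welsh-Corgie on chromosome 2, from 39015994 to 39030767, and -3.61 in Basset Hound on chromosome 38, from 15843268 to 15847835. In Pointer the strongest call was the chromosome 18 gain, at 1.07 from 14239218 to 14420457. All 6 overlapped a region also called in an array against the Boxer. With 1 array per breed these calls have no replicate, and the Pointer array was the noisiest of all, at 0.50 log2 units.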

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

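The tests of hybridisation round, of the dye effect in the seizure bins, of a difference between cases and controls there, of the dye effect in the shared regions and of the spread of their cores between dogs were chosen only after the results were seen. Of 45 tests for an array far from the rest of its group, 3 met the limit, and chance alone picks about 1 in 20 groups.

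German Shepherd 2 had a median green signal of 110.686, against 84.1 in the next German Shepherd. German Shepherd 5 had 5 X chromosome calls, against 2 in the next. The Pointer seizure array (replicate 5) had a noise of 0.499757 log2 units, against 0.296 in the next seizure array. Segments of X beyond the pseudoautosomal part, which no comparison of the report uses, held 37 calls in the other 30 arrays and 0 in the self-self array.

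The 35 bins that set German Shepherds apart from the panel were weighed first. Of 100 splits of the 23 arrays, 1 gave as many bins, the real one, and the highest other gave 1. A random grouping is thus argued against, but 100 splits cannot give a share below 1 in 100. Such splits also break up breed and round together. Round is confounded with breed except in German Shepherd 2 of round 1: at 34 bins called without it, its median position from the panel (0) to the other German Shepherds (1) was 0.651, against -0.135 to 0.069 in the round 1 panel dogs. A single array excludes nothing, so round and breed cannot be told apart. In 60% of the bins (21) a single probe carried over 50% of the difference, so probe effects such as a sequence variant under 1 probe could account for many of them, and less so for the bins on chromosomes 4, 21 and 27 (30.6% to 36.8%).

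The 45 bins shifted in the seizure arrays were weighed next. Of 32 sign flips of the 6 arrays, 1 gave as many, the real one, and the highest other gave 0. Random signs are thus argued against, but 32 flips cannot give a share below 1 in 32. A dye or probe effect could account for the shift: the self-self array, with the same DNA in both channels, had a median ratio of 0.949 to the seizure mean. Over all bins that array correlated with the seizure arrays at -0.14 (Basset Hound) to 0.745 (Blackmouth Cur, of the same slide, day and breed), with 0.625 in Pointer and 0.496 in Mix on other slides and days, and without the Blackmouth Cur seizure array the median ratio was 0.947. A difference between cases and controls is argued against as the cause: the 24 arrays against the Boxer had the same sign in all 45 bins and a median ratio of 1.13 to the seizure mean.

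For the regions shared by most arrays against the Boxer, a dye effect is argued against by the self-self array, whose median ratio to the mean of the 24 arrays was -0.011 over the 10 regions. The copy number of the Boxer as the only difference is argued against at 9 of the 10 cores, where the 23 dogs spread more than the 99th percentile of windows outside the regions, and of windows drawn anywhere on the autosomes; at the chromosome 6 core from 50074590 they did not. Cores called in 11 to 15 arrays were partly picked for differing between dogs, but 3 of the 4 cores called in 18 or more arrays spread as widely. The median ratio of the seizure arrays, -0.081 (from -0.77 to 0.80), decides nothing, since cases and controls of a breed would average near 0 either way. A copy number state of the Boxer together with differences between the other dogs could account for the regions and stays open.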

How the results depend on the processing

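Chosen only after results were seen were the self-self profile, round and scan day as blocks, labels permuted within slides, the self-self array as a group of 1, X without its pseudoautosomal part, and leaving out single German Shepherds, panel dogs or seizure replicate 5 from the calls; the other alternatives were fixed before the data were examined. The difference in calls between German Shepherds and panel kept its direction and its side of 0.05 in 12 of 13 alternatives; at a minimum log2 ratio of 0.5 it was -3.75 (p = 0.0292). The X ratio kept its call in all 3, from -0.92 to -0.54. Similarity lost its call over all autosomal bins (0.0026) and with Spearman (0.0077). The cause was not tested.

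Calls over all arrays (499) became 811 at a minimum of 0.2, 783 at 3 probes, 1383 with the penalty halved and 251 with it doubled. The number of self-self calls (1) changed in 7 of the 10 alternatives fixed before the data were examined. Copy number regions (119) became 75 with normexp, 210 at 3 probes, 79 at 10 probes, 477 with the penalty halved and 63 with it doubled. Seizure calls (132) became 346 at 0.2, 71 at 0.5, 461 and 65 with the penalty halved and doubled, 98 with the self-self profile regressed out and 117 without replicate 5. Looser and stricter thresholds move counts by construction.

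German Shepherd bins (35; 11 higher, 24 lower) became 75 at 3 probes per bin, 10 at 10 probes, 15 at a minimum difference of 0.4, 56 with normexp (40 higher, 16 lower; 12 of the 35), 53 with the self-self profile regressed out, 2 with round as a block, 4 with scan day as a block and 12 with scan day as a random block. Leaving out an array gave 16 to 50: 22 without German Shepherd 1, 16 without 8, 21 without 3, 22 without 6, 22 without 5, 21 without panel Pointer and 23 without panel Redbone. Scan day as a block compares only German Shepherd 2 with the Australian Shepherd, 1 array each, so the 0.14 it gave at the chromosome 21 bin from 29756788 does not reverse the group difference. Of the 20 named bins, 20 lost their call with round as a block (9 with a difference as large or larger, such as chromosome 27 at -2.07 and chromosome 20 at -1.57; standard errors rose 2.44 times), 19 with scan day as a block (those same 2 arrays), 10 with scan day as a random block, 3 with slide as a block and 10 with normexp.

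Seizure bins (45) became 79 at 3 probes per bin, 23 at 10, 181 with normexp, 80 with the self-self profile regressed out, 881 with the self-self array subtracted (539 higher, 342 lower, none of the 45; the noise of that single array enters all 6 differences) and 0 with it as a group of 1, a fit with little power. Leaving out an array gave 22 to 70: 70 without replicate 1, 29 without 2 and 22 without 4. The chromosome 31 bin from 40777506 was 0.0905 with the self-self array subtracted and with it as a group of 1, which take off the same value. The self-self array stood at -1.37 there, slightly below the seizure mean of -1.28. The cause of the changes in the number of bins was not tested.

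No array of the 23 dogs was above the noise limit, so leaving out noisy arrays there changed nothing, and the gene list overlap and its alternatives were not run. No paired analysis was possible because the groups compared share no numbers in their labels. Slides entered as blocks, in labels permuted within slides and as slide means taken off. At least 97.3% of probes were well above background in at least 1 channel, which does not show whether a weak single channel limits an array. The Pointer seizure array had a median red signal of 38.7 against 160.5 in green, and the highest noise, 0.50 log2 units.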

Other observations

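The test whether a panel dog served as seizure control and the test on the pair of regions were chosen only after the results were seen, as were the X regions named here; the tests of carry-over and of same-breed pairs were written down before their results were seen.

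Calls on X are relative to the median of X in the same array, which lies near 0.86 in females. A stretch from 40693511 to 40758748 was called as a loss in 5 arrays, all female, with calls from -0.43 to -0.61; against the Boxer females averaged 0.47 ± 0.11 there and males -0.11 ± 0.09 (SD). A stretch from 120979043 to 121011901 was gained in German Shepherds 1, 2, 4 and 8 and in no panel dog, at a mean of 0.95, the call of German Shepherd 1 reaching from 120649750 to 121765345. Separate calls between 123881080 and 125883488 joined over 20 arrays, with losses in 17 and gains in German Shepherd 5 (also lost in part) and the seizure arrays Blackmouth Cur, Lab and Mix.

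Hypothesis: copies of the same sequence are placed at both the chromosome 9 and the chromosome 2 region that vary together. If so, arrays without Boxer DNA should show the same tie. In the 6 seizure arrays r was 0.998 and the largest difference 0.13. The wolf, at 0.40 and -0.19, departs from the tie, so the hypothesis could hold for dogs only. The cores on chromosome 27 from 48709040 and chromosome 35 from 3079584 met the same expectation. In the seizure arrays their r was 0.987 and their largest difference 0.13. Their spread over the 24 arrays was smaller (SD 0.14 and 0.13 against 0.49 and 0.47). Meeting the expectation thus does not single out copies of 1 sequence, and the hypothesis stays open. The array cannot show where the extra copies lie.

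Hypothesis: the panel dog of a breed also served as the case or the control of the seizure array of that breed. The 6 same-breed pairs had a mean absolute r of 0.353 over 2088 bins, against 0.191 over all 720 pairings (exact one-sided permutation p = 0.00139, the smallest possible), and all 6 r were negative, from -0.58 to -0.17. The panel dogs of Basset Hound, Pointer and Welsh-Corgie had a higher absolute r with the seizure array of another breed (0.261, 0.261 and 0.325 against 0.228, 0.210 and 0.172), so only those of Blackmouth Cur, Lab and Mix were closest to their own breed. A dog in the reference channel would turn its own calls over. At 8 regions called in a single panel dog and no other of the 24 arrays, the median ratio of the seizure to the panel value was -0.399. Of the 8, 6 had the opposite sign. Not all were private to that dog. The 24 arrays averaged -0.66 at the Basset Hound call on chromosome 14 from 55015963 and -0.44 at the Blackmouth Cur call on chromosome 8 from 13296157. The clearest were the Mix on chromosome 21 from 40754292 (-2.87 and 3.07) and the Pointer on chromosome 2 from 83652323 (0.94 and -1.11). There the 24 arrays averaged -0.15 and 0.02. Relatives of the panel dogs among the controls could give the same signs.

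Hypothesis: DNA of an earlier round carried over on reused slide positions. Over 16 pairs the mean correlation with the array before was 0.367, against 0.364 in permuted assignments (one-sided permutation p = 0.409), so no carry-over was seen, though a small one cannot be excluded.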
